A study of Homo sapiens with 18 samples.

How the data were processed

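Ramos cells, an established human B-cell lymphoma line, had been treated with mannitol, zinc acetate, motexafin gadolinium (MGd) or MGd with zinc acetate, and their RNA had been read on 18 Affymetrix HG-U133 Plus 2.0 arrays. The deposited values were probe set signal intensities on a linear scale, 1 value for each of 54675 probe sets on each array. Per the submitters' processing notes these signals came from GCOS, the manufacturer's scanner and signal software; its version, its settings and its summarisation method were not given in the sources used here. The 18 arrays were grouped by the treatment in their labels into 6 groups of 3. The labels did not say whether the 3 arrays of a group came from separate cultures, so p-values measure the spread between these samples. The number of arrays limits the precision of every value.

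The 2% trimmed mean of the arrays ran from 74.7 to 139.6, a range of 58.1% against a tolerance of 5%, so the deposited signals had not been brought to a common level. Each array was scaled to the median trimmed mean of 112, values under the pooled 20th percentile (a signal of 3.72) were set to it, and log2 values were taken. A probe set was kept when its signal lay above the pooled median of 18.0 on at least 3 arrays, and the 62 control probe sets were left out. The platform annotation named exactly 1 gene for 41097 probe sets, several for 1801 and none for 11777; 41043 of the single names matched a RefSeq gene symbol and no symbol needed updating. For each gene the kept single-gene probe set with the highest mean log2 signal was tested, which gave 13789 genes out of 26408 kept probe sets. Probe sets with several genes or none were tested apart and give no gene a value.

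All 18 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group, an intensity trend in the variance, empirical Bayes moderation and 12 residual degrees of freedom. The 13 two-sided comparisons were each treatment against mannitol, MGd with zinc against the same zinc dose and against MGd, the higher zinc dose against the lower with and without MGd, and the interaction of MGd with each zinc dose, which asks whether the joint change differed from the sum of the separate changes. The sum was taken over log2 changes, so it stands for a product of fold changes. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 13789 genes were called higher or lower. Gene groups came from 25 lists written from general knowledge: metallothioneins with the zinc exporter, other zinc transporters, NRF2 antioxidant, heat shock, ATF4 stress, unfolded protein response, hypoxia, glycolysis, p53 target, pro-apoptotic, anti-apoptotic, DNA replication, mitosis, ribosome biogenesis, ribosomal protein, proteasome, oxidative phosphorylation, cholesterol synthesis, immediate early, NF-kB target, B cell and plasma cell genes, and markers of T and NK cells, of myeloid cells and of epithelial cells and fibroblasts. Of the 13 myeloid markers 2 were measured, too few for a test; the other 24 lists were tested in every comparison with camera of the limma package, 312 tests adjusted together, once with a preset correlation between genes of 0.01 and once with an estimated one. Camera asks whether a list moved relative to all other genes.

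The fits, thresholds, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took, per comparison, the called genes whose 3 arrays in one group did not overlap the 3 of the other, the 8 highest and the 8 lowest by log2 change, of which fewer may be printed in that order; for the interactions the adjusted p alone. It added up to 4 members with the smallest p of each list described, and 20 preset stress, zinc and lymphoma genes, 19 of them measured; HSPA1A lay on shared probe sets alone. A gene printed outside that rule is marked as chosen after its values were seen. Metallothionein genes have near-identical sequences, so their probe sets can read paralogs. The same steps were tested on simulated data with the means and spreads of these arrays, in the comparison of 25 µM zinc with mannitol. Each probe set was drawn independently, so the simulated arrays held no correlation between genes. With a log2 change of 0.5 given to 65 genes, 32 were recovered (49.2%); with a change of 1, 37 of 66 (56.1%); with a change of 2, 42 of 65 (64.6%). Of 116 calls 5 were false, and an unchanged comparison gave 0 calls. Camera of limma gave a shifted list an unadjusted p = 7.61e-29, while 0 of 24 other lists had an unadjusted p under 0.05. Without correlation between genes, these counts of false calls say little about those on the real arrays.

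Other settings tried were quantile normalization, centring each array on its median, no filter or a stricter one (pooled 75th percentile), no floor, a pseudocount in place of the floor, no variance trend, the mean of a gene's probe sets, all probe sets, only the arrays compared, a block for replicate number, the estimated correlation, and leaving out each array in turn. Chosen after seeing the data were a scaling on the hybridization controls, a floor at the pooled median, the beta-actin signal ratio as a covariate, and 2 further gene lists. Control ratios were compared with exact permutation tests. Scanned images and cell-level measurements were not analysed here.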

Results

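Transcript levels were measured in Ramos cells, a line grown from a Burkitt lymphoma and used as a model of malignant B cells. The cells received mannitol, a sugar alcohol that served as the control treatment, zinc acetate at 25 or 50 µM as a source of zinc ions, MGd, or MGd with either dose of zinc acetate. MGd is a gadolinium-containing expanded porphyrin that reacts with cellular reducing agents. Each of the 6 treatments had 3 arrays; the MGd concentration and the exposure time were not given in the sources used here. The series asked how MGd and zinc, alone and together, change gene expression relative to mannitol, with oxidative stress and cell death responses as its stated subject. The signal correlation between arrays of one group was 0.940 to 0.960, and between arrays of different groups 0.920 to 0.958. Changes are given as log2 differences ± standard error (SE). They compare 3 arrays with 3, except for the interactions, which draw on the arrays of further groups. Each SE rests on the gene's moderated variance from the fit of all arrays together. It is therefore not the spread of the compared arrays alone. Signals are given as mean ± SD of 3 arrays after scaling. The number of arrays limits the precision of changes and signals. Where a group's signals lay mostly under the pooled median (dim), the size of a log2 change depends on the floor. For many such genes the change with a higher floor at that median is given as well or in its place. That setting was chosen after seeing the data. Where it is not given, as for some values of HMOX1, the size rests on the usual floor. Gene lists carry the count of called members, the count adjusted over the list alone, and adjusted p-values of camera; of a pair of list p-values the first used the preset correlation between genes and the second an estimated one.

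The 6 arrays with 50 µM zinc also stood apart from the other 12 in control measures of how the RNA had been prepared. The ratio of 3' to 5' signal of dap, a bacterial transcript added to the samples, was 1.59 ± 0.104 (SD, n = 6) with 50 µM zinc and 2.70 ± 0.339 (SD, n = 12) on the other arrays. For beta-actin of the cells the ratio was 1.25 ± 0.0674 (SD, n = 6) against 1.73 ± 0.194 (SD, n = 12). An exact two-sided permutation test over 18564 splits of the arrays gave p = 5.39e-05 for each of these ratios, the smallest value it can give. It took single arrays as exchangeable although they came in treatment groups, so it does not test groups as units. The control ratios were chosen after the result was seen. Comparisons between 50 µM zinc and lower doses held this difference beside the zinc dose; comparisons within the 50 µM arrays did not. The mannitol arrays differed from the lower doses in the beta-actin ratio as well: 1.98 ± 0.254 with mannitol, against 1.65 ± 0.0569 with 25 µM zinc, 1.65 ± 0.0966 with MGd and 1.64 ± 0.0929 with both (SD, n = 3 each). Single arrays lay between 1.72 and 2.23 with mannitol, 1.59 and 1.70 with 25 µM zinc, 1.54 and 1.72 with MGd, and 1.57 and 1.75 with both, so comparisons with mannitol held a difference in this ratio at every dose.

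**Figure D1:**
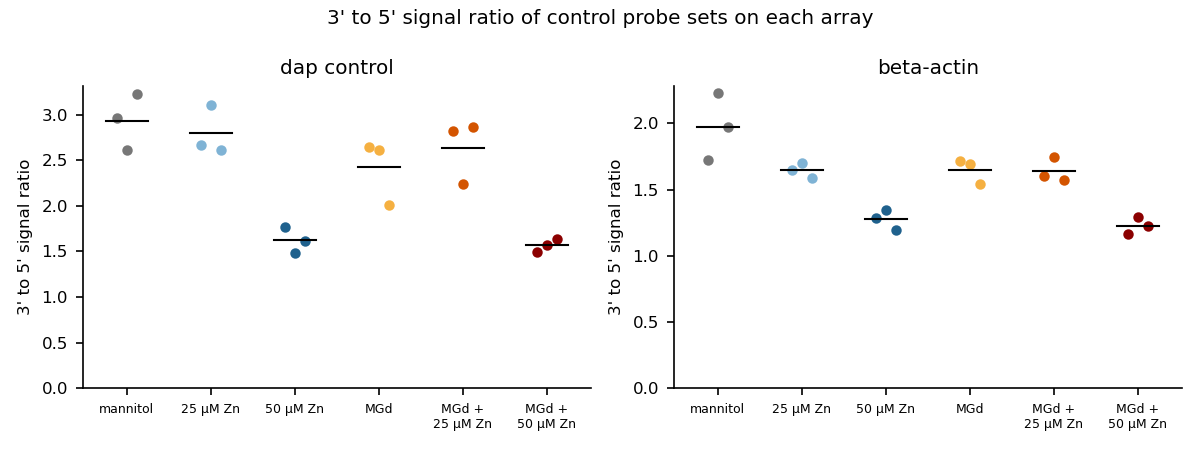
The 3' to 5' signal ratio (no unit) of the added dap transcript and of beta-actin for each of the 18 arrays, by treatment group; points are arrays and bars are the means of 3. For dap the 6 arrays with 50 µM zinc lay between 1.48 and 1.77 and the other 12 between 2.01 and 3.23.

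The number of genes that passed the test ranged from 6 with 25 µM zinc to 4086 with MGd and 50 µM zinc, each against mannitol. MGd alone changed 102 genes and 50 µM zinc alone 1604, while MGd with 25 µM zinc changed 2227.

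**Figure D2:**
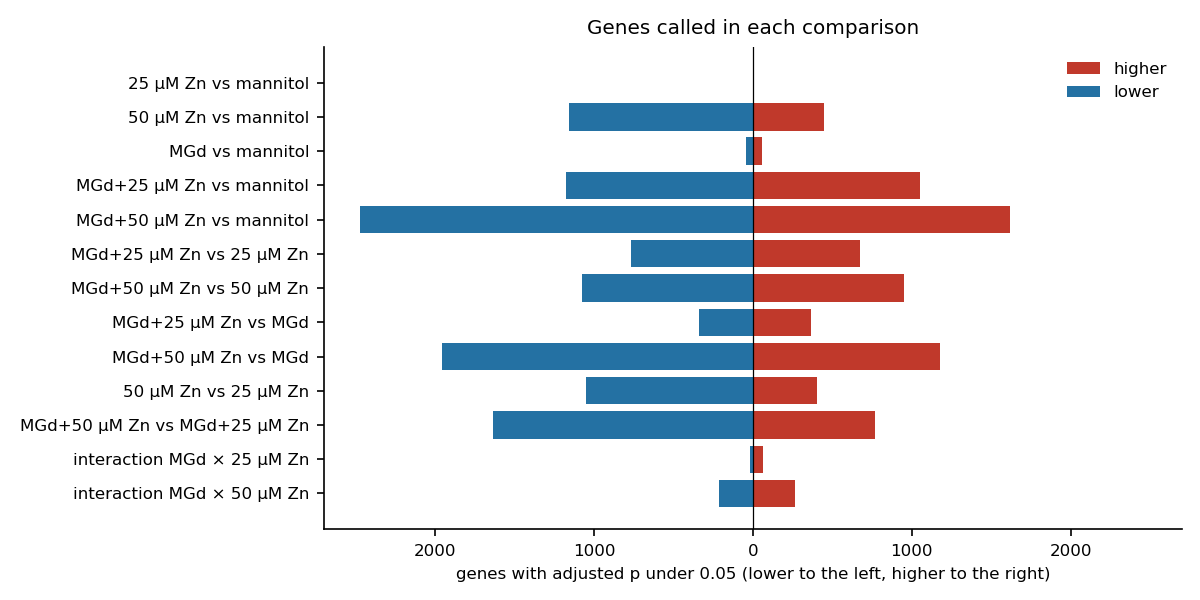
Number of genes called higher or lower at an adjusted p under 0.05 in each of the 13 comparisons, out of 13789 genes tested. Bars give the count in each direction, from 5 higher and 1 lower for 25 µM zinc against mannitol to 1616 higher and 2470 lower for MGd with 50 µM zinc against mannitol.

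The comparison of 25 µM zinc with mannitol asked what the lower zinc dose did alone. The zinc exporter SLC30A1 rose from a signal of 214 ± 9.28 to 741 ± 96.9, a log2 change of 1.78 ± 0.08 (adjusted p = 2.8e-12). The other genes that rose encode metallothioneins, small proteins that bind zinc and other metals: MT1F by 1.49 ± 0.18, MT1H by 1.02 ± 0.12, MT1X by 0.90 ± 0.10 and MT1HL1, dim with mannitol, by 1.76 ± 0.31 (1.29 and not called with the higher floor). BIK, a pro-apoptotic member of the BCL2 family, was the single gene that fell (-0.45 ± 0.08). In the list of metallothioneins and the zinc exporter 4 of 8 measured genes rose, 5 over the list alone, and the list moved up relative to all other genes (adjusted p = 4.72e-17 and 0.000111). The hypoxia genes, targets of the oxygen-sensing HIF factors, also moved up as a list (median 0.12, adjusted p = 0.000112 and 0.00413); limma called 0 of 21 over all genes, 3 over the list alone and 6 at an unadjusted p under 0.05. Of these, KDM3A changed by 0.29 ± 0.06 and BNIP3 by 0.22 ± 0.05 without passing the test over all genes. Stress genes of the preset list were not called, with HMOX1 at 10.5 ± 5.25 against 9.19 ± 11.5 and ATF3 at 30.2 ± 1.49 against 24.1 ± 2.79. Without mannitol replicate 1 the count of 6 became 17, without mannitol replicate 3 it became 15, and without zinc replicate 1 of this dose 24; BIK lost its call without mannitol replicate 2 (log2 change -0.47) or 3 (-0.41) and without zinc replicate 2 (-0.40) or 3 (-0.41), and MT1HL1 without mannitol replicate 3 (1.29). The beta-actin ratio of 1.65 against 1.98 with mannitol, and that of thr, another added transcript, of 3.05 ± 0.209 against 2.59 ± 0.358 (SD, n = 3 each), stood beside these changes. Fitted on the arrays of these groups alone 3 genes were called, 1 higher and 2 lower, and of the calls above only that of SLC30A1 was kept.

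The comparison of 50 µM zinc with mannitol asked what the higher zinc dose did alone. Metallothioneins and zinc transport genes were among the large changes: MT2A rose from 77.4 ± 21.9 to 643 ± 82.5 (log2 change 3.08 ± 0.15), MT1X by 2.87 ± 0.10, MT1H by 3.30 ± 0.12 and SLC30A1 by 2.88 ± 0.08. MT1HL1 rose from a dim 14.6 ± 6.71 to 401 ± 28.7, and MED18, a subunit of the Mediator complex, from a dim level (at least 1.53 with the higher floor). SLC39A10, which carries zinc into cells, fell from 125 ± 8.41 to 17.4 ± 4.58 (-2.70 with the higher floor), and the growth factor gene IGF1 fell from 34.4 ± 2.72 to a dim level (-0.93 with that floor). Limma called 445 genes higher and 1159 lower; the lower share depended on the choice of probe set, since the mean of each gene's probe sets gave 922 higher and 678 lower. Of the metallothionein and exporter list 7 of 8 members rose (adjusted p = 5.26e-25 and 3.44e-05). Of 21 hypoxia genes 10 rose, 11 over the list alone, among them the HIF prolyl hydroxylase EGLN1 (1.02), the collagen prolyl hydroxylase P4HA1 (0.62) and the mitophagy receptor BNIP3 (0.47); the adjusted p of the list was 1.4e-13 and 6.3e-05. The beta-actin ratio of 1.28 ± 0.0738 with 50 µM zinc against 1.98 ± 0.254 with mannitol (SD, n = 3 each) stood beside each of these groups and those that follow.

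Part of the amino acid and oxidant stress response rose with 50 µM zinc. Of the 27 ATF4 stress genes, which are switched on when protein synthesis is restrained under stress, 8 rose (9 over the list alone), with DDIT4, an inhibitor of mTORC1 signalling, at 1.91 ± 0.10, SESN2 at 1.13 ± 0.18 and the transcription factor ATF3 at 1.08 ± 0.18. The adjusted p of the list was 4.4e-09 and 0.00756, with a median of 0.14 that turned to -0.03 with median centring. Of the 21 NRF2 antioxidant genes 4 rose (5 over the list alone): the cystine importer SLC7A11 (1.23 ± 0.13), the glutathione synthesis enzyme GCLC (0.56), the autophagy receptor SQSTM1 (0.49) and the thioredoxin reductase TXNRD1 (0.37). Its adjusted p was 2.33e-05 and 0.00467; its median of 0.14 turned to -0.04 with median centring, and with averaged probe sets SQSTM1 turned to -0.0036. Genes of ribosome biogenesis fell, 13 of 28 (14 over the list alone; adjusted p = 5.73e-06 and 0.0127). Examples were BYSL (-0.46), NOP2 (-0.41) and DDX21 (-0.34). Cholesterol synthesis genes fell as well, 7 of 19 (10 over the list alone; adjusted p = 8.73e-05 and 0.011). Examples were the cyclase LSS (-0.57) and the epoxidase SQLE (-0.37); averaged probe sets turned LSS to 0.24 and SQLE to 0.093. Heat shock genes were mixed: 5 of 19 rose, such as HSPH1 (0.56), and 1 fell, the chaperone partner DNAJB1 (-0.52, with its other probe set at 0.25); the adjusted p of 0.000296 became adjusted p = 0.248 with an estimated correlation. Median centring, which took the median of all genes to -0.22, gave 216 higher and 3811 lower, and scaling on the hybridization controls 188 and 287. Leaving out 50 µM zinc replicate 3 left 1008 calls, and with the beta-actin ratio as a covariate, an alternative chosen after seeing the data, 15; among the genes it no longer called were SLC39A10 (log2 change -3.02) and SLC7A11 (1.10).

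Set directly against 25 µM zinc, the 50 µM dose showed how the zinc response grew with dose. MT1HL1 (3.15 ± 0.31), MT2A (2.35 ± 0.15) and MT1H (2.28 ± 0.12) were among the largest increases. TXNRD2, a mitochondrial thioredoxin reductase, fell on 1 of its 2 probe sets, from 45.8 ± 14.7 to a dim 8.85 ± 1.93 (-1.29 with the higher floor); the other changed by 0.65, and with both averaged the gene was not called (-0.85). The higher dose raised 7 of 8 metallothionein and exporter genes (adjusted p = 1.67e-19 and 7.39e-05), 10 of 21 hypoxia genes (1.79e-09 and 0.000198) and 10 of 27 ATF4 genes (2.43e-12 and 0.00262), with STC2 at 0.86 and CTH at 0.40. It lowered 9 of 28 ribosome biogenesis genes (1.98e-05 and 0.0162), with NOP16 at -0.42 and PES1 at -0.65, and 6 of 33 mitosis genes while 1 rose (0.000471 and 0.0341), with the anaphase activator CDC20 at -0.44 and the phosphatase CDC25B at -0.33. Over the list alone the counts were 7, 11 and 15 higher for the first lists, and 14 and 8 lower for the others. The dap ratio differed between these doses as well, 1.62 ± 0.143 with 50 µM and 2.79 ± 0.269 with 25 µM (SD, n = 3 each), beside every group of genes. In all, 405 genes were higher and 1048 lower; median centring, with the median of all genes at -0.20, gave 183 and 3746, the hybridization controls, which took it to -0.14, 111 and 1248, and averaged probe sets 738 and 621. The count of 1453 became 873 without 25 µM zinc replicate 2, 940 without 50 µM replicate 1, 877 without 50 µM replicate 3, and 143 with the beta-actin covariate.

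MGd without added zinc was compared with mannitol to show what the drug did alone. Genes that handle zinc were again among the large increases: SLC30A1 went from 214 ± 9.28 to 1631 ± 65.1 (2.93 ± 0.08), MT2A rose by 2.49 ± 0.15, MT1F by 2.50 ± 0.18 and MT1X by 2.29 ± 0.10. The zinc importer SLC39A10 fell from 125 ± 8.41 to 14.4 ± 7.32 (-2.70 with the higher floor), and DDIT4 rose by 2.39 ± 0.10. C2orf72 (-1.59 ± 0.25) and RCBTB2 (-0.87 ± 0.13) followed among the genes that fell. Of the metallothionein and exporter list 6 of 8 members rose, 7 over the list alone (adjusted p = 2.2e-37 and 2.39e-05). Hypoxia genes rose, 9 of 21 (11 over the list alone; adjusted p = 1.5e-16 and 3.44e-05). Among them were EGLN1 (0.84 ± 0.06), the histone demethylase KDM3A (0.69 ± 0.06) and the glycolysis regulator PFKFB3 (0.71 ± 0.08). The ATF4 list moved up (median 0.11, adjusted p = 5.11e-07 and 0.0162) with 2 of 27 members called, DDIT4 and ATF3 (0.81), and 6 over the list alone. The NRF2 list moved up likewise (median 0.11, adjusted p = 1.26e-05 and 0.00402); 2 of 21 members rose, SLC7A11 (0.91 ± 0.13) and SQSTM1 (0.36), and 4 over the list alone. The ribosome biogenesis list moved down (adjusted p = 3.01e-05 and 0.018), with 2 of 28 members called, POLR1B (-0.40) and BYSL (-0.31), and 5 over the list alone. HMOX1, DDIT3 and DNAJB1 did not pass the test here, with log2 changes of 0.09, 0.20 and 0.43; with all probe sets tested, 1 of 2 for DNAJB1, at 0.43 and 0.62, was called. Beside each of these groups the beta-actin ratio was 1.65 with MGd and 1.98 with mannitol, that of dap 2.42 ± 0.359 and 2.93 ± 0.309, and that of phe, another added transcript, 2.03 ± 0.363 and 2.63 ± 0.407 (SD, n = 3 each). Of 102 genes 60 rose and 42 fell; median centring gave 48 and 195, the hybridization controls 19 and 4, and the beta-actin covariate 20 calls. The count became 61 and 60 without mannitol replicate 2 and 3, and 46, 56 and 57 without MGd replicate 1, 2 and 3. ATF3, SQSTM1 and BYSL lost their calls without several single arrays, for instance MGd replicate 2 (log2 change 0.70, 0.34 and -0.32), and with averaged probe sets ATF3 (0.17), C2orf72 (-0.28) and POLR1B (-0.26) were not called.

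MGd with 25 µM zinc was compared with mannitol to show the joint change at the lower zinc dose. Metallothioneins rose, MT2A from 77.4 ± 21.9 to 1571 ± 161 (4.38 ± 0.15) and MT1X by 4.31 ± 0.10; SLC30A1 rose by 3.58 ± 0.08 and DDIT4 by 3.77 ± 0.10. LRRC32, a surface protein that binds latent TGF-beta, rose from a dim 4.88 ± 0.144 to 66.0 ± 9.39. SLC39A10 fell to a dim level (-2.79 with the higher floor). Heat shock genes, which encode protein-folding chaperones, rose in 15 of 19 cases (17 over the list alone; adjusted p = 3.41e-15 and 0.0156). Examples were the co-chaperone BAG3 (1.62 ± 0.14), DNAJB1 (1.18 ± 0.11) and HSPB1 (0.94 ± 0.10). Of the ATF4 stress genes 20 of 27 rose (23 over the list alone; adjusted p = 3.16e-19 and 0.000381). Examples were ATF3 (2.36 ± 0.18, on 1 of its 3 probe sets) and the glutathione-degrading CHAC1 (1.23 ± 0.11). Of the NRF2 antioxidant genes 10 of 21 rose (15 over the list alone; adjusted p = 8.12e-13 and 0.000127): SLC7A11 by 2.40 ± 0.13, SQSTM1 by 1.13, TXNRD1 by 1.05 and the sulfiredoxin SRXN1 by 0.87. Hypoxia genes rose in 13 of 21 cases (14 over the list alone; adjusted p = 6.21e-17 and 3.44e-05). Examples were EGLN1 (1.55) and adrenomedullin, ADM (1.52). Of the unfolded protein response genes 6 of 20 rose (6 over the list alone; adjusted p = 0.000125 and 0.0488). Among them were the endoplasmic reticulum chaperone HSP90B1 (0.80) and the disulfide isomerase PDIA4 (0.60). Ribosome biogenesis genes fell in 17 of 28 cases (19 over the list alone; adjusted p = 1.57e-12 and 0.000796). Examples were RRS1 (-1.07 ± 0.11) and POLR1B, a subunit of RNA polymerase I (-0.74). The pro-apoptotic list was split, 4 of 17 higher and 3 lower (adjusted p = 0.653): PMAIP1 rose by 0.86 ± 0.11 and HRK by 0.67 ± 0.14, while BIK fell (-0.72 ± 0.08). BCL6, a repressor that marks germinal-centre B cells, rose by 0.20 ± 0.05, a call lost without replicate 2 of the joint treatment (log2 change 0.17). Of 2227 genes 1049 rose and 1178 fell, a split of 756 and 1427 with median centring; the hybridization controls gave 984 calls and the beta-actin covariate 1114. The beta-actin ratio of 1.64 against 1.98 with mannitol stood beside each of these groups.

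Against 25 µM zinc alone, MGd with 25 µM zinc showed what the drug added at that dose. MT1X rose from 151 ± 19.3 to 1603 ± 263 (3.40 ± 0.10), MT2A by 3.65 ± 0.15, DDIT4 by 3.45 ± 0.10 and SLC30A1 by 1.79 ± 0.08. SLC39A10 fell from 39.6 ± 2.80 to 11 ± 6.42, and BCAR3 fell as well (-1.49 ± 0.22). Of 27 ATF4 stress genes 21 rose (24 over the list alone; adjusted p = 7.08e-27 and 0.000118). Examples were CHAC1 (1.48 ± 0.11), ATF3 (2.04 ± 0.18) and the secreted stanniocalcin STC2 (1.70 ± 0.17). Heat shock genes rose in 14 of 19 cases (16 over the list alone; adjusted p = 8.24e-18 and 0.00999). Examples were DNAJB1 (1.46 ± 0.11), HSPH1 (1.17 ± 0.10) and BAG3 (1.55 ± 0.14). NRF2 genes rose in 11 of 21 cases (13 over the list alone; adjusted p = 9.68e-15 and 9.08e-05). Examples were SLC7A11 (2.16 ± 0.13), TXNRD1 (0.86) and SRXN1 (0.76). Hypoxia genes rose in 12 of 21 cases (1.61e-16 and 3.44e-05) and unfolded protein response genes in 6 of 20 (4.11e-07 and 0.0133); over the list alone the counts were 14 and 11. NF-kB target genes moved up as a list (median 0.19, adjusted p = 0.00153 and 0.0133), with 5 of 18 called on both scales of adjustment, among them lymphotoxin beta, LTB (0.65), and the inhibitor NFKBIA (0.49). Ribosome biogenesis genes fell in 16 of 28 cases (22 over the list alone; adjusted p = 4.56e-15 and 0.000335). Examples were RRS1 (-1.08 ± 0.11) and UTP15 (-0.93 ± 0.12). In total 672 genes rose and 765 fell, 466 and 1057 with median centring, and 156 and 1050 with the hybridization controls, which took the median of all genes to -0.13; averaged probe sets gave 952 calls. Beside each of these groups the phe ratio was 2.61 ± 0.335 with MGd and 25 µM zinc and 2.08 ± 0.228 with 25 µM zinc (SD, n = 3 each), with no overlap of single arrays (lowest 2.39 against highest 2.33).

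MGd with 50 µM zinc was compared with mannitol to show the joint change at the higher zinc dose, and it changed the most genes, with 1616 higher and 2470 lower. HMOX1, the haem-degrading enzyme of the oxidant response, rose from a dim 9.19 ± 11.5 to 233 ± 31.5 (at least 3.58 with the higher floor), and ATF3 from 24.1 ± 2.79 to 552 ± 76.2 (4.51 ± 0.18). DDIT3, a transcription factor of the endoplasmic reticulum stress response, rose from 146 ± 11.3 to 965 ± 30.7 (2.73 ± 0.11), and DNAJB1 from 899 ± 84.4 to 4194 ± 122 (2.23 ± 0.11). MT2A rose by 5.44 ± 0.15, MT1X by 5.10 ± 0.10, SLC30A1 by 4.32 ± 0.08 and DDIT4 by 4.92 ± 0.10. SLC39A10 fell (-2.57 ± 0.40), and the transcription factor MYC fell from 3534 ± 204 to 2714 ± 64.0 (-0.38 ± 0.07). CDKN1A, the p53-induced cell-cycle inhibitor, went from a dim 8.76 ± 5.95 to 33.9 ± 17.2, and NQO1 differed by 0.72 ± 0.28; limma's adjusted p of 0.0622 and 0.0552 missed the threshold, while with all probe sets tested 1 of 2 for NQO1, at 0.72 and 1.64, was called.

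**Figure D3:**
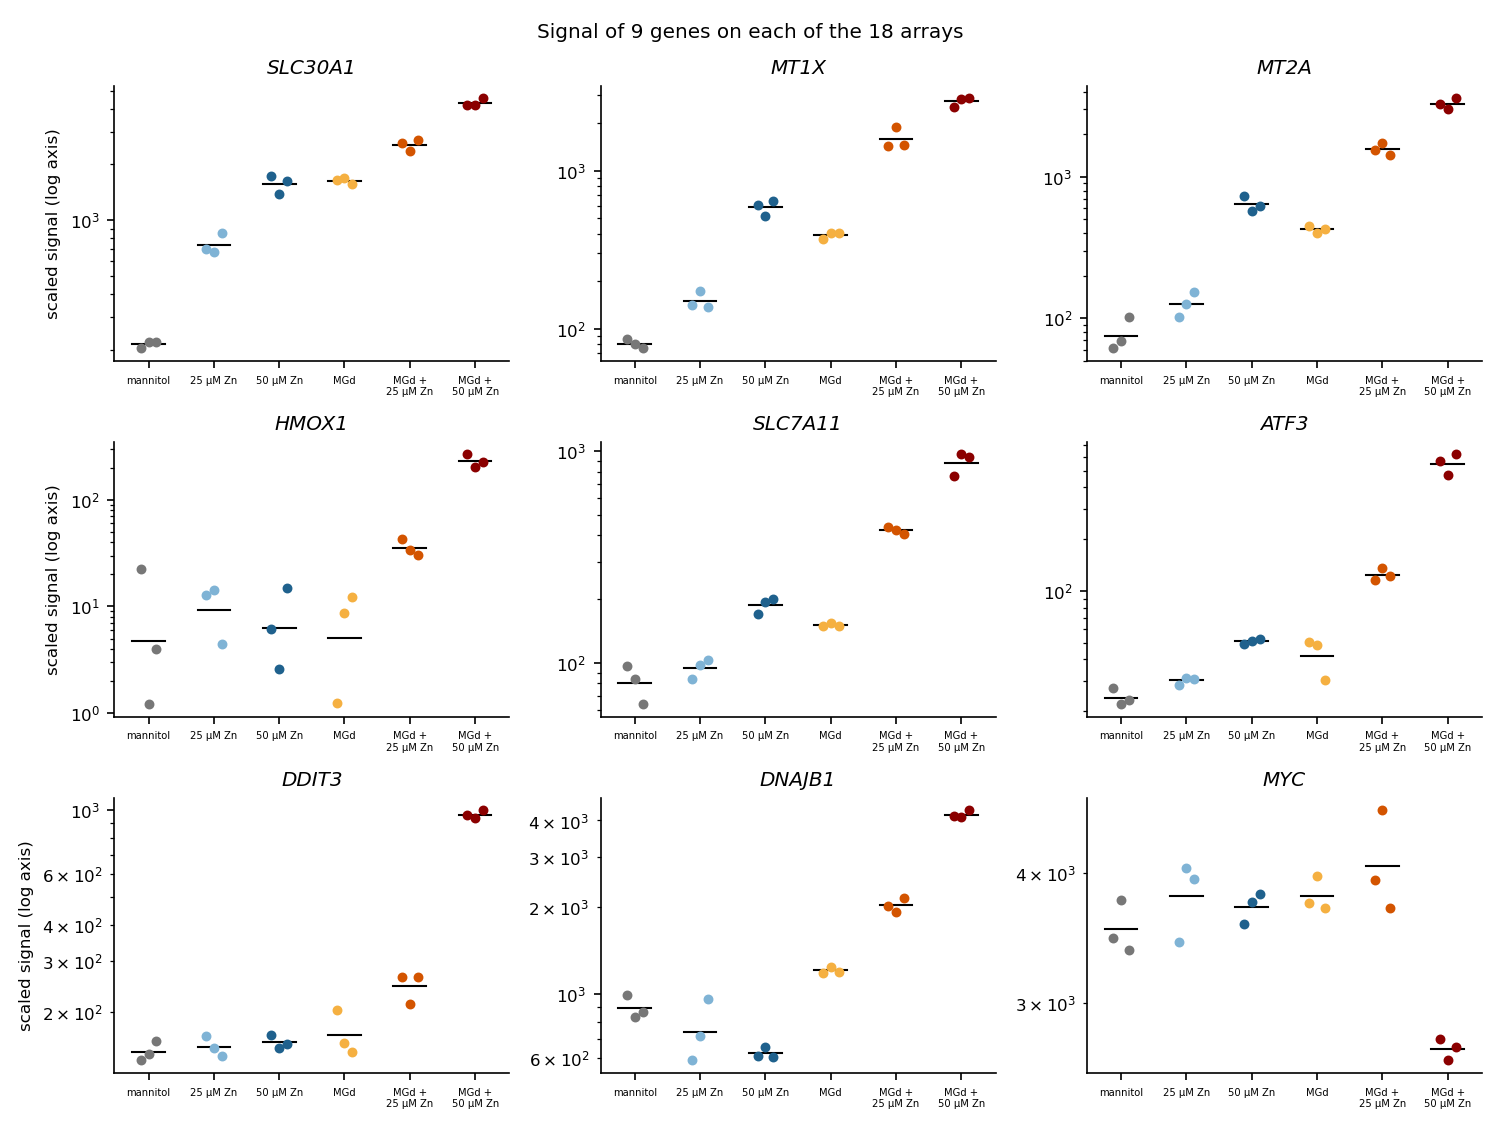
Scaled signal (log axis, arbitrary units, before the floor) of 9 preset genes on each of the 18 arrays, by treatment group; points are arrays and bars are geometric means of 3. SLC30A1 is already high with MGd alone, while DDIT3 and HMOX1 are highest with MGd and 50 µM zinc, at mean signals of 965 and 233.

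Stress lists rose, those of ATF4 and heat shock genes nearly whole. Of 27 ATF4 stress genes 25 rose (26 over the list alone; adjusted p = 1.49e-29 and 9.08e-05). Examples were CTH, which makes cysteine (1.79 ± 0.08) and TRIB3 (1.69 ± 0.10). Of 19 heat shock genes 17 rose (18 over the list alone; adjusted p = 8.15e-20 and 0.00724). Examples were BAG3 (3.01 ± 0.14), HSPB1 (2.06 ± 0.10) and HSPH1 (1.75 ± 0.10). Of 21 NRF2 antioxidant genes 12 rose (13 over the list alone; adjusted p = 3.65e-11 and 0.000214). Examples were SLC7A11 (3.46 ± 0.13), GCLM, a subunit of the glutathione synthesis enzyme (1.27 ± 0.10) and TXNRD1 (1.02). The metallothionein and exporter list had 7 of 8 members higher (8.48e-18 and 9.75e-05), the hypoxia list 11 of 21 (2.71e-09 and 0.000205), led by EGLN1 at 1.71; these counts were 7 and 11 over the list alone. Ribosome biogenesis genes fell in 21 of 28 cases and rose in 1 (22 and 1 over the list alone; adjusted p = 6.2e-12 and 0.000987). Examples were RRS1 (-1.83 ± 0.11) and POLR1C (-1.22 ± 0.08). Mitosis genes fell in 19 of 33 cases and rose in 2 (19 and 3 over the list alone; adjusted p = 4.6e-05 and 0.016). Examples were CDC20 (-1.03 ± 0.06) and cyclin B1, CCNB1 (-0.57). Cholesterol synthesis genes fell in 11 of 19 cases and rose in 1 (13 and 1 over the list alone; adjusted p = 0.00315 and 0.043). Examples were LSS (-1.07 ± 0.09) and SQLE (-0.68). The dap ratio was 1.57 ± 0.0690 on these arrays and 2.93 ± 0.309 with mannitol (SD, n = 3 each), beside every list named here. Median centring, which took the median of all genes to -0.19, gave 802 higher and 4123 lower, the hybridization controls, which took it to -0.21, 570 and 3649, and averaged probe sets 1893 and 1622; with the beta-actin covariate 585 genes were called, HMOX1 (1.17) and MYC (-0.14) no longer among them.

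Further lists were called only with the preset correlation or not at all. Unfolded protein response genes rose in 10 of 20 cases and fell in 2, with HSP90B1 at 1.18 and SEL1L at 0.50; the adjusted p of 0.000157 became adjusted p = 0.051 with an estimated correlation, and the median of 0.20 turned to -0.01 with the hybridization controls. Immediate early genes rose in 9 of 20 cases and fell in 3 (adjusted p = 0.000158, adjusted p = 0.0741 with an estimated correlation), with JUND at 1.01. Ribosomal protein genes rose in 29 of 31 cases by a median of 0.29, such as RPS19 (0.39), with adjusted p = 2.27e-13 but adjusted p = 0.217 with an estimated correlation. Glycolysis genes rose in 8 of 13 cases and fell in 1 (0.00843, adjusted p = 0.333 with an estimated correlation), with aldolase A, ALDOA, at 0.47; their median of 0.20 turned to -0.01 with the hybridization controls. Pro-apoptotic genes were split, 4 of 17 higher and 4 lower (adjusted p = 0.664), with PMAIP1 at 1.45 ± 0.11, HRK at 1.37 ± 0.14 and FADD at -0.66; anti-apoptotic genes had 5 of 11 higher and 1 lower (0.238), with MCL1 at 0.32 and TNFAIP8 at -0.71. The p53 targets had 3 of 17 higher and 3 lower (0.593), with TP53INP1 at 0.85, and the DNA replication genes 12 of 36 higher and 10 lower (0.493), with the flap endonuclease FEN1 at -0.93 and the licensing factor CDT1 at 0.74. B cell genes fell in 12 of 32 cases and rose in 5 (0.139), with the kinase SYK at -0.90 ± 0.07 and the transcription factor IKZF3 at -1.21 ± 0.10, which averaged probe sets turned to 0.33. Plasma cell genes had 5 of 12 higher and 1 lower (0.255), with XBP1 at 0.50, turned to -0.018 by averaged probe sets. NF-kB targets had 6 of 18 higher and 4 lower (0.0984), proteasome genes 9 of 29 higher and 5 lower (0.207), oxidative phosphorylation genes 4 of 33 higher and 7 lower (0.873), and zinc transporters 3 of 19 higher and 3 lower (0.558). Markers of T and NK cells, 1 of 10 lower (0.634), and of epithelial cells and fibroblasts, 1 of 8 higher (0.708), did not move as lists.

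Against 50 µM zinc alone, MGd with 50 µM zinc showed what the drug added at that dose, between arrays with like dap ratios (1.57 ± 0.0690 and 1.62 ± 0.143, SD, n = 3 each). Other measures, taken before scaling, differed beside the changes that follow. The 18S signal was 158 ± 26.5 with MGd and 249 ± 55.0 without, with no overlap of single arrays. The trimmed mean signal was 85.6 ± 9.88 and 106 ± 14.6 (SD, n = 3 each). Because the 18S signals were not scaled, they also carry the difference in the trimmed mean. HMOX1 rose from a dim 7.90 ± 6.34 to 233 ± 31.5, the phosphatase DUSP5 from a dim 10.1 ± 7.11 to 110.5 ± 9.97 and the transcription factor JUN from 18.7 ± 13.9 to 102 ± 31.3. With the higher floor these changes were at least 3.68, 2.61 and 2.09; ATF3 rose by 3.43 ± 0.18. DDIT3 rose by 2.62 ± 0.11, DNAJB1 from 625 ± 28.3 to 4194 ± 122 (2.75 ± 0.11), BAG3 by 2.74 ± 0.14 and DDIT4 by 3.01 ± 0.10. MYC fell (-0.45 ± 0.07), and the dim TSPAN10 fell from 37.7 ± 10.5 to 7.67 ± 1.64. Of 27 ATF4 stress genes 26 rose (26 over the list alone; adjusted p = 2.2e-37 and 4.57e-05). Examples were CHAC1 (1.94 ± 0.11) and TRIB3 (1.47 ± 0.10). Of 19 heat shock genes 16 rose (17 over the list alone; adjusted p = 2.31e-24 and 0.00359). Examples were HSPB1 (1.74 ± 0.10) and HSPA4 (0.75). Of 21 NRF2 genes 10 rose (12 over the list alone; adjusted p = 8.48e-12 and 0.000182). Examples were SLC7A11 (2.23 ± 0.13) and GCLM (1.03 ± 0.10). Metallothionein and exporter genes rose in 7 of 8 cases (7 over the list alone; adjusted p = 1.18e-17 and 9.75e-05), with MT1X at 2.23 ± 0.10. Hypoxia genes rose in 8 of 21 cases and fell in 1 (8 and 1 over the list alone; adjusted p = 0.000497 and 0.00756). Examples were EGLN1 (0.70) and hexokinase, HK2 (-0.56). Immediate early genes rose in 10 of 20 cases and fell in 2 (10 and 3 over the list alone; adjusted p = 2.33e-05 and 0.0477). Examples were JUND (0.96), ZFP36, which destabilises cytokine transcripts (1.08) and DUSP1 (1.70). Ribosome biogenesis genes fell in 13 of 28 cases and rose in 1 (17 and 2 over the list alone; adjusted p = 1.87e-11 and 0.00112). Examples were RRS1 (-1.46 ± 0.11) and POLR1C (-1.06 ± 0.08). Mitosis genes fell in 12 of 33 cases and rose in 2 (14 and 3 over the list alone; adjusted p = 0.00021 and 0.0255). Examples were the mitotic kinesin KIF20A (-0.53) and CDC20 (-0.51). Among cell death genes PMAIP1 rose by 0.75 ± 0.11 and HRK by 1.02 ± 0.14, while the pro-apoptotic list as a whole was not called (0.416). Of 2029 genes 953 rose and 1076 fell; scaling on the hybridization controls, which took the median of all genes to -0.20, gave 217 and 2356.

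**Figure D4:**
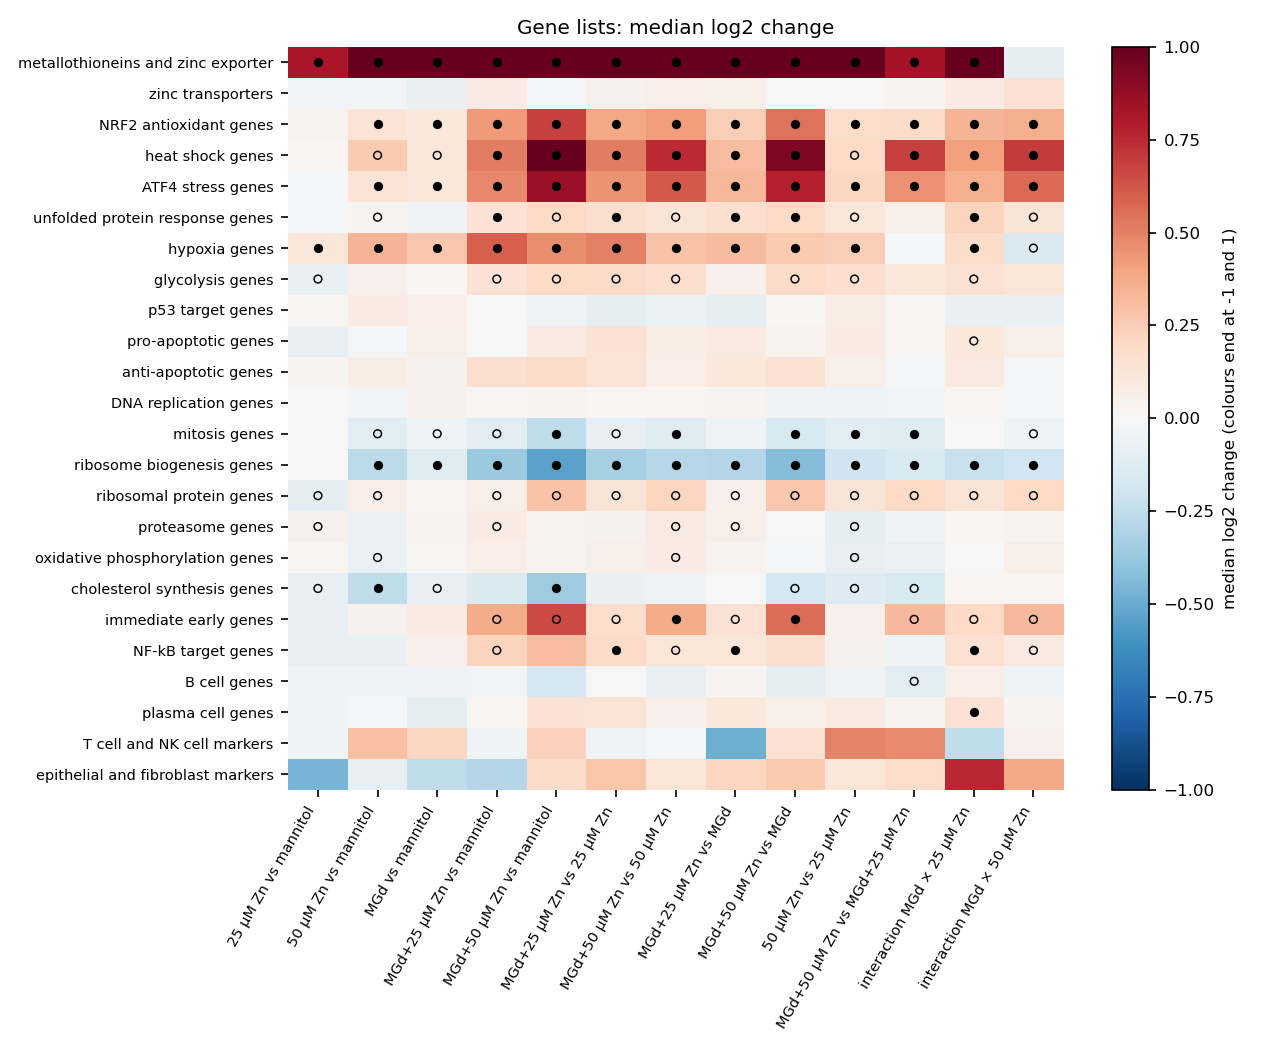
Median log2 change of each of the 24 gene lists (no unit beyond log2; colour scale ending at -1 and 1) in each of the 13 comparisons. A filled circle marks a list called with the preset and the estimated correlation, and an open circle one called with the preset correlation alone, as all calls of the ribosomal protein genes are; for MGd with 50 µM zinc against 50 µM zinc their median of 0.21 turned to -0.0031 with quantile normalization.

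Zinc added to MGd was compared with MGd alone to show what zinc did in drug-treated cells. With 25 µM zinc, MT1H rose by 2.47 ± 0.12, MT1X by 2.02 ± 0.10, MT2A by 1.88 ± 0.15 and SLC30A1 by 0.65 ± 0.08, and the dim RHPN1 fell from 38.1 ± 3.06 to 6.46 ± 1.93. HMOX1 went from 7.41 ± 5.63 to 35.8 ± 6.42 (at least 0.98 with the higher floor; with the usual floor adjusted p = 0.041), a call lost without any array of either group but MGd replicate 3, for example without MGd replicate 1 (log2 change 1.78). ATF4 stress genes rose in 15 of 27 cases (9.84e-21 and 0.000274), with ATF3 at 1.56 ± 0.18 and CHAC1 at 0.87, and heat shock genes in 10 of 19 (5.42e-16 and 0.0133), with BAG3 at 1.13 ± 0.14 and HSPB1 at 0.79. NRF2 genes rose in 8 of 21 cases (1.71e-12 and 0.000139), with SLC7A11 at 1.49 ± 0.13 and TXNRD1 at 0.76, and hypoxia genes in 8 of 21 (1.11e-10 and 0.000127), with EGLN1 at 0.71. Lower were 10 of 28 ribosome biogenesis genes (3.1e-11 and 0.0012), with RRS1 at -0.72 and NOP2 at -0.40. Over the list alone the counts were 22, 15, 12, 11 and 18 in that order. Of 706 genes 366 rose and 340 fell, 426 and 247 with median centring; the count became 415, 393 and 406 without MGd replicate 1, 2 and 3, and 350 without replicate 2 of the joint treatment. No variance trend gave 379 calls, averaged probe sets 397 and the hybridization controls 161. The phe ratio of 2.61 ± 0.335 against 2.03 ± 0.363 with MGd (SD, n = 3 each), with no overlap of single arrays (lowest 2.39 against highest 2.30), stood beside these lists.

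With 50 µM zinc added to MGd, stress genes rose as well. HMOX1 rose from 7.41 ± 5.63 to 233 ± 31.5 (at least 3.68 with the higher floor), ATF3 by 3.71 ± 0.18, MT2A by 2.95 ± 0.15 and DDIT3 by 2.53 ± 0.11, while MYC fell (-0.49 ± 0.07) and TFAP4 fell from 34.6 ± 3.89 to a dim 7.49 ± 1.63. ATF4 stress genes rose in 26 of 27 cases (8.49e-35 and 5.77e-05), heat shock genes in 17 of 19 (9.63e-23 and 0.0045), with BAG3 at 2.51 ± 0.14, and NRF2 genes in 11 of 21 (6.6e-11 and 0.000234), with SLC7A11 at 2.55 ± 0.13. Unfolded protein response genes rose in 11 of 20 cases and fell in 1 (4.03e-06 and 0.0206), with XBP1 at 0.69 ± 0.07, turned to -0.12 by averaged probe sets; their median of 0.20 turned to -0.04 with the hybridization controls. Ribosome biogenesis genes fell in 21 of 28 cases and rose in 1 (9.22e-12 and 0.00104), with RRS1 at -1.48 ± 0.11, and mitosis genes fell in 15 of 33 and rose in 3 (9.45e-05 and 0.0194), with CDC20 at -0.77 ± 0.06. Over the list alone 26 ATF4, 18 heat shock, 11 NRF2 and 13 unfolded protein response genes rose, and 21 ribosome biogenesis and 18 mitosis genes fell. The dap ratio of 1.57 ± 0.0690 against 2.42 ± 0.359 with MGd (SD, n = 3 each) stood beside each of these groups. Of 3135 genes 1178 rose and 1957 fell; median centring, with the median of all genes at -0.13, gave 676 and 3094, the hybridization controls, which took it to -0.25, 325 and 3680, and averaged probe sets 1310 and 1275. The beta-actin covariate left 973 calls, without HMOX1 (log2 change 2.53).

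MGd with 50 µM zinc was also set against MGd with 25 µM zinc, the zinc dose response in the presence of the drug. HMOX1 rose by 2.71 ± 0.64, DUSP5 by 2.42 with the higher floor, ATF3 by 2.15 ± 0.18, DDIT3 from 247 ± 29.7 to 965 ± 30.7 (1.97 ± 0.11) and TRIB3 by 1.40 ± 0.10. MYC fell from 4073 ± 459.6 to 2714 ± 64.0 (-0.58 ± 0.07) and BCL6 fell (-0.23 ± 0.05). CDKN1A rose from a dim 3.33 ± 1.25 to 33.9 ± 17.2 (at least 0.78 with the higher floor; with the usual floor adjusted p = 0.0111), a call lost without replicate 3 of the 50 µM joint treatment (log2 change 2.59). ATF4 stress genes rose in 21 of 27 cases (6.93e-26 and 0.000127), heat shock genes in 15 of 19 (1.25e-15 and 0.0143), with HSPB1 at 1.11 ± 0.10, and metallothionein and exporter genes in 7 of 8 (5.53e-09 and 0.00137), with MT2A at 1.07 ± 0.15. NRF2 antioxidant genes rose in 7 of 21 cases (0.00177 and 0.0227), with GCLM at 0.63 ± 0.10; their median of 0.19 turned to -0.0015 with the hybridization controls, and TXNRD1 did not differ past the threshold (-0.02 ± 0.08). The hypoxia list was not called here (0.999, median -0.02). Mitosis genes fell in 15 of 33 cases and rose in 1 (0.000154 and 0.0227), with CDC25B at -0.52 ± 0.06 and KIF20A at -0.56, and ribosome biogenesis genes fell in 11 of 28 and rose in 1 (0.00017 and 0.0311), with NOP16 at -0.62 ± 0.07. Over the list alone 25 ATF4, 15 heat shock, 7 metallothionein and exporter and 9 NRF2 genes rose, and 15 mitosis and 11 ribosome biogenesis genes fell. The dap ratio of 1.57 ± 0.0690 against 2.64 ± 0.350 (SD, n = 3 each) stood beside each of these groups. Of 2403 genes 770 rose and 1633 fell; median centring, with the median of all genes at -0.16, gave 389 and 3368, the hybridization controls, which took it to -0.21, 205 and 2955, averaged probe sets 1072 and 993, and the beta-actin covariate 400 calls, with HMOX1 no longer among them (log2 change 0.31).

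The interaction of MGd with 25 µM zinc asked whether the joint change differed from the sum of the separate log2 changes, a product of fold changes. MT1H (1.45 ± 0.17) and MT1X (1.11 ± 0.15) rose more than the sum, SLC30A1 less (-1.14 ± 0.12). Beyond the sum were also STC2 (1.59 ± 0.24), the amino acid transporter SLC38A2 (1.34 ± 0.13), SLC7A11 (1.25 ± 0.18) and DNAJB1 (1.03 ± 0.15); below it was FASTKD2, a mitochondrial RNA-binding protein (-0.82 ± 0.13). Among the lists, ATF4 genes lay above the sum by a median of 0.36 (5 of 27 called, 17 over the list alone; adjusted p = 9.63e-23 and 0.000204). An example was CHAC1 (1.12 ± 0.16). NRF2 genes did by 0.34 (5 of 21, and 7; 9.19e-11 and 0.000243), with TXNRD1 at 0.57 ± 0.11 and SRXN1 at 0.63 ± 0.12, and heat shock genes by 0.41 (5 of 19, and 10; 9.07e-15 and 0.0164), with HSPH1 at 1.02 ± 0.14. Ribosome biogenesis genes lay below it by a median of -0.22 (1 of 28, and 3; 3.57e-09 and 0.0029). HMOX1 (1.84 ± 0.91) and DDIT3 (0.50 ± 0.16) did not pass this test. Means of control ratios did not add up across these groups either, beside each of these lists, though this was not tested against their spread. With mannitol, 25 µM zinc, MGd and both, the phe ratio was 2.63, 2.08, 2.03 and 2.61. The beta-actin ratio was 1.98, 1.65, 1.65 and 1.64 in that order (means of 3). Of 79 genes 62 lay above and 17 below the sum; the hybridization controls, which took the median of all genes to -0.16, gave 9 calls, no filter 48, no variance trend 33, averaged probe sets 34 and the beta-actin covariate 24. The count became 50 without mannitol replicate 2, 37 without zinc replicate 1, 44 and 36 without MGd replicate 1 and 3, and 41 without replicate 2 of the joint treatment. TXNRD1 lost its call without zinc replicate 1 (log2 change 0.48) and MGd replicate 1 (0.51) or 3 (0.52), and with averaged probe sets SLC7A11 (0.59) and SLC30A1 (-1.10) were not called.

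At 50 µM zinc the interaction test, which asked the same question, was passed by more genes. ATF3 exceeded the sum by 2.62 ± 0.26, DDIT3 by 2.42 ± 0.16 and DNAJB1 by 2.31 ± 0.15. HMOX1, dim in the other groups of this test, exceeded it too (3.79 with the higher floor; the size depends on the floor). Below the sum were SLC30A1 (-1.49 ± 0.12), MYC (-0.56 ± 0.10), DBR1, which opens intron lariats (-1.30 ± 0.18), and TUBGCP5, a nucleator of microtubules (-1.22 ± 0.17). Of 27 ATF4 stress genes 20 lay above the sum (25 over the list alone; adjusted p = 8.66e-36 and 5.44e-05). Examples were CHAC1 (1.58 ± 0.16) and TRIB3 (1.40 ± 0.14). Of 19 heat shock genes 12 did (16 over the list alone; adjusted p = 2.17e-24 and 0.00359). Examples were BAG3 (2.25 ± 0.19) and HSPB1 (1.59 ± 0.15). Of 21 NRF2 genes 6 lay above it (8 over the list alone; adjusted p = 8.8e-08 and 0.00105), with SLC7A11 at 1.32 ± 0.18 and GCLM at 0.97 ± 0.14. Ribosome biogenesis genes lay below the sum in 6 of 28 cases (9 over the list alone; adjusted p = 1.39e-06 and 0.00924). Examples were RRS1 (-1.11 ± 0.16) and POLR1C (-0.82 ± 0.12). MT1X (-0.06 ± 0.15) and MT2A (-0.13 ± 0.21) did not differ from the sum past the threshold, and the metallothionein list was not called (0.558). Here too the means of control ratios did not add up, though this was not tested against their spread. With mannitol, 50 µM zinc, MGd and both, the dap ratio was 2.93, 1.62, 2.42 and 1.57. The beta-actin ratio was 1.98, 1.28, 1.65 and 1.23 in that order (means of 3). Of 478 genes 265 lay above and 213 below the sum; median centring gave 382 and 134, the hybridization controls, which took the median of all genes to -0.23, 43 and 403, and no variance trend 299 calls.

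**Figure D5:**
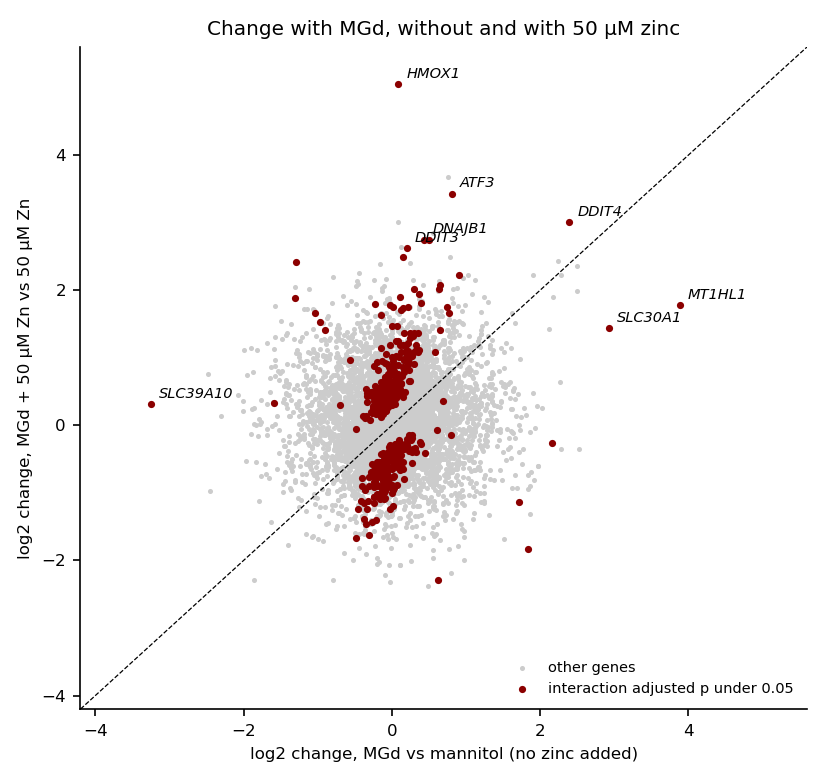
Log2 change with MGd against mannitol (x axis) and log2 change with MGd and 50 µM zinc against 50 µM zinc (y axis) for each of the 13789 genes; red points passed the interaction test and the dashed line marks equal changes. ATF3 lay at 0.81 and 3.43, and SLC30A1 below the line at 2.93 and 1.44.

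The genes that MGd changed overlapped between zinc doses in comparisons that shared no array. These comparisons did share the variance estimate of each gene, so calls need not be independent even without a shared change. The expected counts may therefore be too low. Of the genes called with MGd and 25 µM zinc against 25 µM zinc and with MGd and 50 µM zinc against 50 µM zinc, 383 were higher in both, where 46.4 would be expected if the calls were independent, and 457 were lower in both (59.7 expected); 3 went in opposite directions. MGd against mannitol shared 46 higher genes (2.92 expected) and 35 lower genes (2.33 expected) with MGd and 25 µM zinc against 25 µM zinc. With MGd and 50 µM zinc against 50 µM zinc it shared 38 higher genes (4.15 expected) and 29 lower genes (3.28 expected), and 2 went in opposite directions. The step from 25 to 50 µM zinc shared 33 higher genes (1.76 expected) and 25 lower genes (3.19 expected) with MGd against mannitol. Control ratios fell in both of these comparisons. The dap ratio was 1.62 against 2.79 in the zinc step and 2.42 against 2.93 with MGd. The beta-actin ratio was 1.28 against 1.65 and 1.65 against 1.98.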

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

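The interaction tests were planned; the probe sets without a single gene, the control ratios and, for the patterns weighed in this part, the tests of scaling and probe set choice on falling genes and of preparation on stress genes, the look at which splits kept arrays together and the permutations of what the separate changes left over, were chosen only after the result was seen.

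Some changes with MGd and 25 µM zinc together differed from the sum of the separate changes by the interaction test of limma, for 79 of the genes tested. Higher than the sum were MT1X (1.11), MT2A (1.15), TXNRD1 (0.57), SLC7A11 (1.25), SRXN1 (0.63), DNAJB1 (1.03) and ATF3 (1.23), and lower was SLC30A1 (-1.14). Camera called several lists above the sum with the preset and an estimated correlation. Among them were metallothioneins and the zinc exporter (median 1.13), heat shock (0.41), ATF4 stress (0.36), NRF2 antioxidant (0.34) and unfolded protein response genes (0.22). Hypoxia, NF-kB target and plasma cell genes, given below, were called above it as well. Ribosome biogenesis genes were called below it (-0.22). Of the metallothionein and exporter list 4 of 8 members were called above and 1 below (5 and 1 over the list alone; adjusted p = 5.45e-05 and 0.0127), and of the unfolded protein response list 1 of 20 above (9 over the list alone; 5.55e-09 and 0.00667); the report gives the other counts. Hypoxia genes had a median of 0.18 with 2 of 21 called (4 over the list alone; 0.000159 and 0.00467), NF-kB target genes 0.16 with 1 of 18 (3; 0.00135 and 0.0127) and plasma cell genes 0.15 with 1 of 12 (3; 0.0136 and 0.046). Scaling on the hybridization controls took these hypoxia genes to -0.0007, NF-kB target genes to -0.03 and plasma cell genes to -0.04, along with the median of all genes, which it took to -0.16. Of 100 splits of the 12 arrays 7 called at least as many genes, so chance was not excluded for this count by them. The highest other split called 351, several times the real count. That split and another kept the 3 arrays of the joint treatment in 1 group. Such a split carries the change of the joint arrays against the rest into the tested difference, so its count shows no hidden structure of the samples. The highest split that parted them called 292, and on which side of the difference its joint arrays fell was not examined. With the separate changes kept and what they left over permuted across the arrays, 1 of 100 arrangements, the real one, gave as many calls (highest other 13), which argues against chance where the splits leave it open.

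With MGd and 50 µM zinc 478 genes differed from the sum of the separate changes by the same test. Higher were HMOX1 (4.96), ATF3 (2.62), DDIT3 (2.42), DNAJB1 (2.31), TRIB3 (1.40), SLC7A11 (1.32), GCLM (0.97) and SRXN1 (0.60), and lower were SLC30A1 (-1.49) and MYC (-0.56). The size for HMOX1 depends on the floor, since its signals lay mostly under the filter level in the other groups; with a floor at the pooled median it was 3.79. Heat shock genes lay above the sum by a median of 0.70, ATF4 stress genes by 0.56 and NRF2 antioxidant genes by 0.36, and ribosome biogenesis genes lay below it (-0.19). Of 100 splits of the 12 arrays 3 called at least as many genes; the highest other split called 1893. Such splits also mix the separate changes into the spread, which lowers their counts, so their share of 3 in 100 was not taken to exclude chance. Both other splits that reached the real count, and no further one, kept the 3 arrays of the joint treatment in 1 group. The 97 that parted them called 15 or fewer. The high counts therefore went with the change of the joint arrays against the rest, which such splits carry into the tested difference. With the separate changes kept and what they left over permuted across the arrays, 1 of 100 arrangements, the real one, gave as many calls (highest other 4), which argues against chance for this count.

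The rise of stress genes beyond the sum at 50 µM zinc was set against technical explanations. Over 4 scalings the lowest median interaction of the ATF4 list above all genes was 0.51. Median centring and the hybridization controls shift each array by a constant, which by construction leaves this difference as in the main fit. Only quantile normalization could alter it, so the value argues against scaling for that setting only. A preparation that enlarged every MGd response on the 50 µM arrays alike would need a gain of 5.45 for the ATF4 list. For 98 genes outside the stress lists that MGd alone changed, the change at 50 µM was divided by that alone. The median ratio was 0.84 and the highest 3.21. The 98 genes were picked by their call with MGd alone, which lowers such ratios. The needed gain rests on a small ATF4 change with MGd alone. The ratios go against a gain near 5.45 but leave a smaller common gain open. An equal shift of all 50 µM arrays drops out of the interaction by construction. A preparation that acted on the stress genes alone stays open. Between the sets of 50 µM arrays, with and without MGd, the ATF4 list differed by a median of 0.62. The pattern itself implies that difference. A joint action of MGd and zinc stays open beside such a preparation.

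SLC30A1 rose less than the sum of the separate log2 changes. In signal units its single arrays lay at 203 to 220 with mannitol and 1380 to 1733 with 50 µM zinc. They lay at 1559 to 1685 with MGd and 4159 to 4531 with both. The separate rises added in signal units fall short of the joint rise, so the shortfall holds on the log2 scale only. The highest SLC30A1 signal in the joint treatment was 36.9% of a percentile near the top of that array's signals. That argues against a signal at the top of the array's range of probe set signals. Saturation of single probes stays open, because cell-level measurements were not analysed. A shared zinc signal that both treatments raise, so that their log2 changes do not add, stays a hypothesis that was not tested. The value of 36.9% bears on saturation alone.

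More genes fell than rose at 50 µM zinc against 25 µM zinc. Over 3 other scalings at least 69.3% of the called genes fell, which argues against the choice among these scalings for the brightest probe set of each gene. All 3 kept that probe set, so they cannot separate scaling from the choice of it. The choice of 1 probe set per gene may account for it: with the probe sets of a gene averaged, 45.7% of the called genes fell. Another preparation of the 50 µM arrays stays open, because it coincided with the dose; within groups, the slope of genes on the beta-actin ratio ran with the dose change at a Spearman correlation of 0.0173, which decided nothing. Effects of the zinc dose itself cannot be told apart from that preparation here.

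Outside the genes tested, signals lay above the control as well: 568 kept probe sets without a single annotated gene were called higher with 50 µM zinc against mannitol, and 904 with MGd and 50 µM zinc, beside 169 and 475 called lower. The share called was 10.6% and 19.8%, against 13.9% and 28.3% of the probe sets with a single gene. The dap 3' to 5' ratio differed by -0.75 on the log2 scale between the 50 µM zinc arrays and the others.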

How the results depend on the processing

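The scaling on the hybridization controls, the floor at the pooled median and the beta-actin covariate were chosen only after the result was seen; the other settings were planned. Of 149 planned counts, leaving out single arrays aside, 127 lay within 1.5 times of the main count, and the cause of the other shifts was not tested. Median centring raised 50 µM zinc against mannitol to 4027 calls, MGd against mannitol to 243, the step between zinc doses to 3929 without MGd and 3757 with it. No filter gave 11 calls for 25 µM zinc against mannitol and 48 for the 25 µM interaction; the stricter filter gave 15 for 25 µM zinc and 160 for MGd. No variance trend lowered MGd to 39, MGd with 25 µM zinc against MGd to 379, the zinc step to 907 and the interactions to 33 and 299. Averaged probe sets lowered MGd with 25 µM zinc to 952 against 25 µM zinc and 397 against MGd, and the 25 µM interaction to 34; all probe sets gave 2792 genes for 50 µM zinc against mannitol and 2357 for the zinc step. Only the arrays compared gave 3 (1 of them a main call), 41 and 48 calls for 25 µM zinc, MGd and the 25 µM interaction. The hybridization controls gave 11 for 25 µM zinc, 475 for 50 µM zinc, 23 for MGd, 984 for MGd with 25 µM zinc, 161 for that treatment against MGd and 9 for the 25 µM interaction. The beta-actin covariate, which is confounded with the 50 µM dose, gave 15 for 50 µM zinc, 20 for MGd, 1114 and 585 for MGd with 25 and 50 µM zinc, 973 for the latter against MGd, 143 and 400 for the zinc steps and 24 for the 25 µM interaction. With an estimated correlation 86 of the 145 list calls were left. Leaving out 1 array gave 17, 15 and 24 calls for 25 µM zinc (mannitol replicate 1 and 3, zinc replicate 1), 1008 for 50 µM zinc (its replicate 3), and 61, 60, 46, 56 and 57 for MGd (mannitol replicate 2 and 3, MGd replicate 1, 2 and 3). It gave 415, 393, 406 and 350 for MGd with 25 µM zinc against MGd, 873, 940 and 877 for the zinc step, and 50, 37, 44, 36 and 41 for the 25 µM interaction, for the arrays named in the report. Without single arrays the counts ran from 5 to 24 for 25 µM zinc, from 1008 to 1433 for 50 µM zinc, from 46 to 92 for MGd, from 350 to 561 for MGd with 25 µM zinc against MGd, from 873 to 1155 for the zinc step and from 36 to 72 for the 25 µM interaction. The labels do not say whether replicate numbers pair the samples, and no sign of it was seen. With group means taken out, 6 of 18 arrays correlated most, on average, with arrays of their own number in other groups. That is the count to be expected without pairing. The mean correlation was 0.00024 for the same number and -0.00012 for another. A block for the number changed no count by over 1.5 times.

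Directions of named genes were reversed in 7 of 8431 alternative values, for 411 pairs of gene and comparison, with 7522 kept calls and 902 lost ones. All pairs had passed the main test, so few reversals were to be expected. Several settings could not reverse a direction at all, since they kept each gene's log2 change of the main fit. These were no variance trend, the replicate block, only the arrays compared, and all probe sets, read on the gene's main probe set. Among the lost calls 138 came with the beta-actin covariate, 67 with averaged probe sets and 394 from leaving out single arrays. With averaged probe sets, 50 µM zinc against mannitol gave LSS 0.24, SQLE 0.093 and SQSTM1 -0.0036, MGd with 50 µM zinc against mannitol gave IKZF3 0.33 and XBP1 -0.018, and against MGd XBP1 -0.12; with the beta-actin covariate CLIC5 in MGd with 50 µM zinc against mannitol turned from -2.31 to 1.53.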

Other observations

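The interferon and autophagy lists and their genes, and the comparison of probe sets within genes, were chosen after their values were seen; the splits of the arrays were planned.

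OAS1, which senses double-stranded RNA and was chosen after its values were seen, fell when MGd was added to 50 µM zinc (-1.08 ± 0.08). Whether genes induced by interferon fell as a group stayed open: without OAS1 and IFIT5, which prompted the list, 4 of 28 measured genes fell and 2 rose, with a median of -0.14 (unadjusted camera p = 0.0772 by limma, and 0.129 with an estimated correlation). GABARAPL1, part of the autophagosome machinery and chosen after its values were seen, rose by 1.06 ± 0.20 in that comparison. Of 27 other autophagy genes, SQSTM1 left out as well, 2 rose and 1 fell, with a median of 0.12 (unadjusted camera p = 0.00984 by limma, and 0.0134 with an estimated correlation); a shift of that list is a hypothesis.

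Outside the genes tested, 3 probe sets each annotated to several heat shock genes rose with MGd and 50 µM zinc against mannitol, by 7.46, 4.76 and 3.43 on the log2 scale; no gene is named for them.

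Among the genes with at least 2 kept probe sets, the other probe sets changed more upward than the brightest at 50 µM zinc, by a median of 0.17 against mannitol (66.8% of genes above) and 0.16 against 25 µM zinc (67.3%); with quantile normalization these were 0.11 (61.1%) and 0.075 (59.3%). Between the sets of 50 µM zinc arrays the median was 0.0054 (50.8%), and for MGd with 25 µM zinc against 25 µM zinc 0.00038 (50.1%), with quantile normalization -0.0089 (48.6%) and -0.021 (46.8%).

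Splits of the arrays of 3 against 3 give only 10 arrangements, too few for a share under 0.05; in each comparison 1 split, the real one, gave as many calls. The real and the highest other count were 6 and 4 for 25 µM zinc against mannitol, 1604 and 4 for 50 µM zinc, 102 and 2 for MGd, 2227 and 0 for MGd with 25 µM zinc, and 4086 and 1 for MGd with 50 µM zinc. Against the same zinc dose they were 1437 and 0 at 25 µM and 2029 and 2 at 50 µM; against MGd 706 and 0, and 3135 and 1; between zinc doses 1453 and 0 without MGd and 2403 and 1 with it. Control measures of other transcripts differed between the 50 µM arrays and the rest as well, by exact permutation tests: gapdh p = 0.00345, thr p = 0.00221, phe p = 0.000916, the trimmed mean signal 95.7 against 116 (p = 0.00673) and the 18S signal 203 against 479 (p = 0.00151).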
